A study of Mus musculus with 94 samples.

How the data were processed

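Whole livers of APOE cKO mice, of D374Y mice and of the littermate controls of each model were profiled by RNA-seq in 94 libraries that fall into 31 groups of 2 to 5. APOE is a ligand that carries lipoprotein remnants into hepatocytes. Per the labels, mice ate chow until day 10 or a high-fat diet (HFD; 21% fat and 0.15% cholesterol) until week 4, 8, 12 or 20. Some groups had also received clodronate liposomes, which kill phagocytes such as Kupffer cells (the resident macrophages of the liver), Dil liposomes, PBS, or an antibody against CD8 (carried by cytotoxic T cells) or CD20 (carried by B cells). Poly(A) RNA was made into libraries with the QuantSeq V2 kit of Lexogen, per the labels. The series calls its replicates biological; the labels do not say which animals shared a litter, cage or library batch, so p-values measure the spread between these samples.

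The deposited files hold raw counts per gene model, 1 file per library, and the values were checked to be whole numbers with a different total in each library, so no normalization by the authors is left in them. The labels name mm10 for 27 libraries (all of week 8 and the day 10 APOE cKO liposome libraries) and mm9 for the other 67. The submitters' processing notes list TopHat 1.4.1, STAR 2.4.2a and HTSeq and the builds mm9, GRCm38 and mm10, with no role or order. The mm9 files hold 24732 gene models, of which 21.8% overlap another, and the mm10 files 25579, of which 53.7% do. Reads of overlapping or closely related genes cannot be told apart from the files, so values of such genes are less certain. Both sets were analysed apart, and CPM levels of different stages are not on a common scale. Total counts ran from 8691802 to 73109190 per library, and CPM values of a few counts carry counting error of that size; counts are not independent molecules, so no confidence interval is given for a level. Among 106 pairs of libraries of the same group, 0 held the same counts and the chi-square per degree of freedom of a pair was at least 2.05 (median 29.8), so all were kept as separate replicates.

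The slope of log2 CPM on log2 exonic length was computed in each library with the exons of a GENCODE annotation. It spanned -0.13 to 0.055 in the mm10 libraries. The mm9 libraries fell into 3 profiles, with slopes of -0.19 to 0.011 in 28, 0.18 to 0.35 in 20 and -0.57 to -0.17 in 19 libraries. Day 10 and week 4 hold more than 1 profile. Comparisons that cross profiles (Dil against untreated D374Y at day 10, with the difference that uses both; PBS against untreated and CD8 against PBS at week 4) cannot separate treatment from library set, and this is stated beside them.

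Each stage (time point and build) was fitted once in edgeR 4.0.16 (limma 3.58.1, R 4.3.3, data.table version 1.17.8) with TMM scaling, filterByExpr (minimum count 10, minimum total 15), a quasi-likelihood F test per gene and a prior count of 0.125, in 7 separate fits, of which 1 holds the untreated mm9 libraries of weeks 4, 12 and 20 for changes with time. A gene is called when its Benjamini-Hochberg adjusted p is below 0.05. Log2 fold changes, in brackets after a gene's name, are given ± their standard error, computed as the size of the change divided by the square root of F, and CPM as mean ± SD. For every called gene given with a value, the libraries of the higher group all lay above those of the lower group, except where "overlapping" stands beside it; this was not asked of differences between models, times or treatments. Where a group of a comparison with controls or with another treatment has a mean below 0.5 CPM, levels are given in place of a fold. Difference tests between models subtract the D374Y effect from the APOE cKO effect. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) made the tables and plots. Overlaps between sets of calls were tested with Fisher's exact test, one-sided, over the genes tested in both comparisons.

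A total of 23 gene lists with 295 members were tested: cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, bile acid synthesis and transport, fatty acid oxidation, lipid droplet, Kupffer cell markers, recruited and lipid-associated macrophage markers, inflammatory cytokines and chemokines, acute phase, interferon response, MHC class II presentation, T and NK cell markers, B and plasma cell markers, neutrophil markers, stellate cell and fibrosis markers, liver sinusoidal endothelial markers, endoplasmic reticulum stress, proliferation, circadian clock, sex-linked, red blood cell and pancreas. In the mm9 files 289 members were matched and 6 were not (Hmgcs1, Trbc2, Ly6g, Hba-a1, Hba-a2 and Amy2a5); in the mm10 files 292 were and 3 were not (Trbc2, Ighm and Ighd). Lists with at least 5 tested members were tested with fry, adjusted over the lists of a comparison. This adjusted value is called the list p. It asks whether the members move, on balance, in one direction; it does not compare a list with other genes. Counts of called members use the adjustment over all genes, and a count "adjusted over the list alone" is given beside them.

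Genes are named by a rule: Apoe in genotype comparisons; per comparison the 5 largest log2 fold changes in each direction among called genes whose groups do not overlap and whose mean is at least 5 CPM in the higher group; per model the 10 genes with the largest mean change in each direction among those called the same way at 3 or more of 4 HFD times (2 or more where fewer than 10 are); up to 4 members with the smallest p of each list that is called or has a called member; and the 5 smallest adjusted p in each direction of the differences between models and times. Symbols that start with Gm and digits, end in Rik or are bare identifiers are counted but not named. The text leaves out some of the genes the rule selects, and says where a gene outside it was chosen after its values were seen.

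The 28 comparisons, the lists, this rule and a first set of alternatives were fixed before the data were examined: DESeq2 1.42.0, RLE scaling, no low-count filter, only the compared groups in the fit, the replicate number as a block, each library left out in turn, and Xist as a covariate where a fit holds both sexes. After the data were seen, 4 comparisons were added (CD8 against untreated D374Y at week 4, and 3 on liposome libraries whose markers go against their labels), as were fits with libraries of one length profile, a fit without 2 libraries together, and overlaps at an adjusted p below 0.1. The edgeR fits were tested on simulated data: with 100 genes changed 2-fold and 100 changed 4-fold, 36 to 76 of the former and 75 to 93 of the latter were recovered in 9 simulated comparisons, and 4 to 13 unchanged genes were called in each. Of 20 or 21 lists per simulated comparison, lists without a planted change passed in 4 of the 9: 3 at the sizes of CD20 against PBS, 2 at those of APOE cKO at week 20 and 1 each at those of APOE cKO at day 10 and of the difference between models at week 8, so some list p values below 0.05 are due to chance. Reads, alignments and other data of the study were not analysed here.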

Results

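RNA levels were read in 94 liver libraries. Untreated littermate controls and APOE cKO mice numbered 4 and 4 at day 10 on chow, then 3 and 3 at week 4, 3 and 5 at week 8, 3 and 4 at week 12 and 2 and 3 at week 20 of HFD. Untreated littermate controls and D374Y mice numbered 2 and 2, 2 and 3, 3 and 5, 3 and 4, and 2 and 4 at those times. Liposome groups at day 10 were APOE cKO with Dil (3) or clodronate (3), D374Y with Dil (3) or clodronate (3) and D374Y littermate controls with clodronate (3). Those at week 8 were D374Y littermate controls with Dil (3) and D374Y with clodronate (2). At week 4, APOE cKO mice received the CD8 antibody (2), and D374Y mice the CD8 antibody (3), the CD20 antibody (3) or PBS (2). Libraries held 8691802 to 73109190 counts. Xist and Ddx3y, a transcript of female cells and a Y-linked gene, put the untreated day 10 and all week 4 libraries in females and the week 12 libraries in males. The APOE cKO series is male at week 8 and female at week 20, and the D374Y series the reverse. Liposome libraries of day 10 are male in the APOE cKO series and female in the D374Y series. The sex-linked list, read within each comparison, had 0 called members in the genotype comparisons.

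The first question was whether Apoe was altered in either model. Apoe (mm9 chromosome 7, 20281593 to 20284515) fell in APOE cKO livers at every time: 806 ± 83.1 against 4761 ± 503 CPM at day 10 (n = 4 and 4), 847 ± 97.3 against 5425 ± 456 at week 4 (n = 3 and 3), 2003 ± 102 against 13750 ± 2703 at week 8 (n = 5 and 3), 2770 ± 108 against 14420 ± 471 at week 12 (n = 4 and 3) and 1206 ± 47.8 against 8877 ± 410.5 at week 20 (n = 3 and 2). Its log2 fold change lay between -2.88 and -2.38, so a part of the transcript remained. In D374Y livers Apoe was not called at any time, with log2 fold changes from -0.32 ± 0.19 at day 10 to 0.13 ± 0.11 at week 20. At week 4 it was 0.10 ± 0.59, at 5014 ± 2570 against 4676 ± 1300 CPM (n = 3 and 2), a spread too wide to exclude a 2-fold change.

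**Figure D1:**
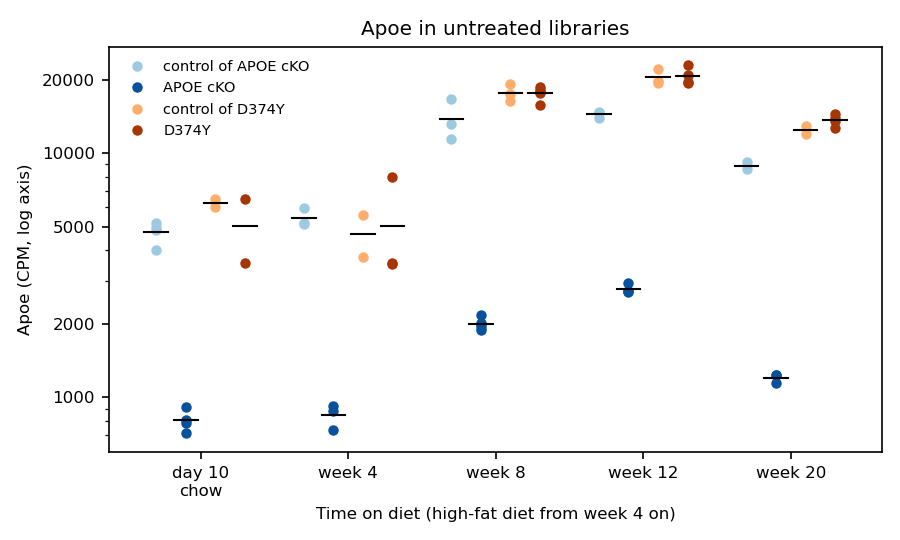
CPM of Apoe in each untreated library, by model, genotype and time, with group means; the vertical axis is logarithmic. Apoe is lower in every APOE cKO group, and the D374Y groups lie near their controls.

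On chow at day 10, before any HFD, APOE cKO livers (n = 4 and 4) differed from controls in 12 genes, and in 1 with only the compared groups in the fit. Cd5l (mm9 chromosome 3, 87161803 to 87174996), a protein secreted by tissue macrophages, rose from 88.3 ± 16.8 to 159 ± 26.2 CPM, and Abcg1 (mm9 chromosome 17, 31194639 to 31254926), a transporter that moves cholesterol out of cells, rose by log2 0.79 ± 0.12. Folr2, the folate receptor of tissue macrophages (0.83 ± 0.15), Themis2 (0.77 ± 0.14) and the interferon-induced Oas3 (1.30 ± 0.16) also rose. Slc10a2, a bile acid transporter (-2.33 ± 0.44), Slc1a5, an amino acid transporter (-1.79 ± 0.31), and Gria3 (-1.01 ± 0.18) fell. The Kupffer cell list rose on balance (adjusted p 0.00287), with 2 of 10 members called higher and 0 lower; adjusted over the list alone, 6 were higher and 1 lower. Clec4f, a lectin of Kupffer cells outside the rule and chosen after its values were seen, had a log2 fold change of 0.51 ± 0.12 (adjusted p 0.114). In all, 12 of 13270 tested genes were called, 6 in each direction, and DESeq2 called 84. The number called was 3 without APOE cKO 1 or 4, 4 without APOE cKO 2, 6 without control 3, 7 without control 4, 19 without APOE cKO 3, 33 without control 1 and 129 without control 2.

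After 4 weeks of HFD, APOE cKO livers (n = 3 and 3) carried more transcripts of lipid-laden macrophages, acute-phase proteins and chemokines. Gpnmb (mm9 chromosome 6, 48986517 to 49008181), a membrane glycoprotein of lipid-laden macrophages, stood at 13.2 ± 0.369 against 0.763 ± 0.592 CPM, and Saa3, a serum amyloid A made by macrophages and hepatocytes, at 49 ± 9.58 against 3.52 ± 0.668. Ccl2, which draws in monocytes, rose to 5.11 ± 1.76 against 1.43 ± 0.465 CPM and Cd5l to 189.5 ± 43.1 against 62.3 ± 7.78. Tmc3 (6.42 ± 4.61 against 0.28 ± 0.309 CPM) and Efr3b (3.67 ± 0.38) were among the largest increases. Cytokines and chemokines rose in 5 of 15 tested members (13 adjusted over the list alone; list test 2.32e-04), with Tnf at 1.89 ± 1.02 against 0.307 ± 0.259 CPM and Cxcl10 at log2 1.30 ± 0.26. Kupffer cell markers rose in 3 of 10 (7 adjusted over the list alone; list p 0.00323), among them Timd4, a receptor for dying cells (1.03 ± 0.19). Recruited macrophage markers rose in 4 of 13 (adjusted over the list alone 7 higher and 1 lower; list p 0.00345), among them Lgals3 (2.04 ± 0.30), Cd68 (1.43 ± 0.24) and the elastase Mmp12 (3.11 ± 0.68). LXR targets rose in 2 of 10 (list p 0.0096), Abcg1 (1.74 ± 0.29) and the lipase Lpl (1.13 ± 0.22). Acute-phase genes rose in 5 of 18 (6 adjusted over the list alone; list p 0.00655), with Saa1, Saa2 (3.18 ± 0.39) and Lcn2 (3.15 ± 0.40). Lists for interferon (list p 0.0487), MHC class II (list p 0.0133), fibrosis (list p 0.0212) and sinusoidal endothelium (list p 0.0282) rose on balance with 1, 0, 1 and 1 called members (Irf7, none, Tgfb1 and Pecam1). The 26 lower genes included Rpl37a (-1.61 ± 0.38) and Llph (-1.72 ± 0.33). Of 13596 genes, 195 were called, 169 higher; the count was 67 without control 1, 90 without control 3 and 81 without APOE cKO 1.

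At week 8 macrophage markers were again higher in APOE cKO livers (n = 5 and 3). Gpnmb stood at 16.5 ± 5.57 against 1.43 ± 0.881 CPM, Cd5l at 354 ± 35.5 against 117 ± 9.92 and Clec4f (mm10 chromosome 6, 83644542 to 83656116) at 249.9 ± 25.3 against 150 ± 13.4. Cyp2a4, a cytochrome P450 with close paralogs (mm10 chromosome 7, 26307192 to 26315088), had the largest increase (4.26 ± 0.66), followed by the scavenger receptor Marco (3.36 ± 0.77), Saa3 (3.27 ± 0.51) and Lcn2 (3.04 ± 0.65). Scd1, which desaturates stearate (-0.90 ± 0.22), the elongase Elovl5 (-0.65 ± 0.15), the lipid transporter Mfsd2a (-1.20 ± 0.27) and Hamp2, a hepcidin gene (-1.26 ± 0.27), fell; of the fatty acid synthesis list 2 of 16 were lower, and the list was not called (list p 0.0556). Kupffer cell markers rose in 5 of 10 members (7 adjusted over the list alone), recruited macrophage markers in 3 of 13 (9 adjusted over the list alone) and cytokines in 4 of 15 (10 adjusted over the list alone), each with a list adjusted p of 0.00729. Examples were Adgre1 (0.90 ± 0.20), Lgals3 (1.72 ± 0.31), Cxcl1 (1.74 ± 0.40) and the interleukin 1 antagonist Il1rn (1.94 ± 0.31). Interferon genes rose in 3 of 16 (10 adjusted over the list alone; list p 0.0225), with Mx1 (0.85 ± 0.18), and LXR targets in 3 of 10 (4 adjusted over the list alone; list p 0.0265), with Abcg1 (1.30 ± 0.16). Of 14357 genes, 276 were called, 249 of them higher; the count was 124 without control 1 and 158 without control 2.

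At week 12, 136 of the 143 called genes were higher in APOE cKO livers (n = 4 and 3). Gpnmb reached 19.2 ± 11.4 against 1.7 ± 0.709 CPM and Cd5l 448 ± 90 against 139.9 ± 25.8. Mmp12 (2.94 ± 0.61), the interferon-induced Gbp2b (2.34 ± 0.26), Il1rn (2.30 ± 0.32) and Saa3 (2.22 ± 0.33) had large increases, and Lmbrd2 (-1.18 ± 0.24) and Cyp39a1, an oxysterol hydroxylase (-1.17 ± 0.26), fell. Recruited macrophage markers rose in 5 of 13 (list p 0.016; 9 higher and 1 lower adjusted over the list alone), with Lgals3 (1.98 ± 0.26) and the lectin Clec7a (1.56 ± 0.28). LXR targets rose in 2 of 10 (list p 0.0134), Abcg1 (1.34 ± 0.17) and Lpl (1.08 ± 0.20). Cytokines (list p 0.0073; 1 called, 9 adjusted over the list alone), interferon genes (list p 0.0161; 2 called, 9 adjusted over the list alone) and MHC class II genes (list p 0.0355; 1 called, 6 adjusted over the list alone) rose on balance. T and NK cell markers did so as a list (list p 0.00658) with 0 called members and 2 adjusted over the list alone. Kupffer cell markers, with Cd5l, Folr2 (1.33 ± 0.28) and Timd4 (1.07 ± 0.24) called higher of 10, gave a list adjusted p of 0.0595. The number called was 32 without control 3, 58 without APOE cKO 2 or 4, 78 without control 2 and 88 without control 1.

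At week 20 more genes were called in APOE cKO livers (n = 3 and 2) than at the other times, which differ in n and sex, but without control 2 the count was 79, fewer than at weeks 4, 8 and 12. Proliferation, fibrosis and macrophage lists rose, and the cholesterol synthesis list fell. Gpnmb stood at 51.8 ± 16.2 against 0.799 ± 0.684 CPM, Trem2, a lipid receptor of macrophages, at 7.39 ± 2.72 against 1.36 ± 0.496, and Cd5l at 736 ± 33.9 against 213 ± 12.2. Col1a2, a chain of type I collagen, stood at 50.3 ± 7.46 against 19.8 ± 1.44 CPM, and Top2a, a topoisomerase of dividing cells, at 19.5 ± 0.53 against 3.23 ± 0.0735. Cyp2b9 (mm9 chromosome 7, 26958428 to 26995679) was at 0.0185 ± 0.032 against 319 ± 12.4 CPM, and its neighbour and relative Cyp2b13 (mm9 chromosome 7, 26846514 to 26881215) at 0.0185 ± 0.032 against 115 ± 17.3; reads that match both cannot be told apart here. Cyp3a16 (-5.57 ± 0.57) and Cyp3a44 (-4.65 ± 0.20) also fell, while Mup20, a urinary protein, rose to 90.6 ± 43.3 against 5.84 ± 0.221 CPM. Cholesterol synthesis fell in 20 of 24 members (23 adjusted over the list alone; list p 0.0102), with Tm7sf2 (-1.65 ± 0.22), Hsd17b7 (-0.80 ± 0.15) and the regulator Srebf2 (-0.55 ± 0.087). Fatty acid synthesis fell in 6 of 16 (15 adjusted over the list alone; list p 0.0209), with Acacb (-1.36 ± 0.37) and Fads1 (-0.96 ± 0.11). Bile acid genes fell in 4 of 13 (list p 0.00338), with Nr0b2 (-1.19 ± 0.35) and the bile salt importer Slc10a1 (-0.58 ± 0.11). Endoplasmic reticulum stress genes fell in 5 of 12 (list p 0.0209), with Creld2 (-1.28 ± 0.24). B cell markers fell in 5 of 12 (adjusted over the list alone 1 higher and 8 lower; list p 0.00843), with Fcer2a (-1.48 ± 0.34).

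Lists that rose at week 20 of APOE cKO were proliferation in 9 of 12 members (11 adjusted over the list alone; list p 0.00131), with Ccnb2 (2.87 ± 0.38). Fibrosis genes rose in 6 of 14 (9 adjusted over the list alone; list p 0.00191), with Col1a1 (1.47 ± 0.24), and LXR targets in 4 of 10 (5 higher and 2 lower adjusted over the list alone; list p 0.00338), with Abcg1 (1.77 ± 0.26). Recruited macrophage markers (list p 0.0152) had 7 higher and 1 lower of 13, and Kupffer cell markers (list p 0.0209) 6 higher and 1 lower of 10. Interferon genes (list p 0.0431) had 8 higher and 1 lower of 16, and MHC class II genes (list p 0.0209) 6 higher of 8. Acute-phase genes had 0 higher and 2 lower of 18, Orm1 (-0.76 ± 0.17) and Fgb (-0.41 ± 0.12), with a median of -0.15, a mean of 0.10 and a downward list test of 0.826. Of 13259 genes, 1044 were higher and 936 lower. The total of 1980 was 496 without control 1, 79 without control 2 and 922 without APOE cKO 1.

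Across the HFD times, 125 genes were called higher in APOE cKO livers at 3 or more of the 4, and 53 at all 4. Those with the largest mean log2 fold change were Tmc3, Gpnmb (4.29), Ifitm6, Saa3 (2.58), Mefv, Gbp2b (2.02), Gfra2, Lgals3 (1.90), Parvg (1.79) and Ccdc148 (1.78). No mean is given for those 4 with controls below 0.5 CPM at some times, where the fold, and so the order, rests on few counts. In the other direction 16 genes were called at 2 or more times, Apoe at all 4 and Cyp2b9, Hamp2, Acpp, Atp4a, H2-Q1, Ccdc61, C5ar2, Elovl2 and Pgrmc2 at 2. Higher genes shared by weeks 4 and 20 numbered 118 where 13.1 were due by chance (Fisher's exact p 7.45e-93), against 4 lower genes where 1.79 were due (0.0996). A direct test of change from week 4 to week 20 called 13 of 13811 genes. Mup20 (difference 4.99 ± 0.54), Ugt2b35, an enzyme of glucuronidation (1.23 ± 0.20), Ccnyl1 (1.76 ± 0.34), the complement gene C8a (1.59 ± 0.31) and Mzt1 (0.76 ± 0.15) moved up. Cyp3a44 (-3.78 ± 0.62), Cyp3a16 (-4.86 ± 0.91), Atp1b3 (-1.27 ± 0.25) and the steroid hydroxylase Cyp17a1 (-2.65 ± 0.55) moved down. The B and plasma cell list moved down (list p 0.0406; 0 of 13 called, 8 adjusted over the list alone). The count was 2 without either week 20 control, 3 without week 20 APOE cKO 1 or 3, 4 without week 4 APOE cKO 1, 5 without week 4 control 1 or 3, 6 without week 4 APOE cKO 2, and 36, 38 and 44 without week 4 control 2, week 4 APOE cKO 3 and week 20 APOE cKO 2.

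D374Y livers on chow at day 10 (n = 2 and 2) differed from controls in 31 of 13270 genes, with no list called. G6pc3, a glucose phosphatase, stood at 7.93 ± 2.19 against 3 ± 0.477 CPM. Prr12 (1.35 ± 0.25), the amino acid transporter Slc7a8 (1.30 ± 0.22), the retinoic acid receptor Rara (1.21 ± 0.22) and the repair gene Ercc1 (1.20 ± 0.24) rose. Gt(ROSA)26Sor, the transcript of the Rosa26 locus, fell to 3.58 ± 0.858 against 10.9 ± 2.03 CPM, and Nop58, a nucleolar protein (-1.15 ± 0.17), fell too. The count was 0 without control 1 (edgeR, 1393 genes at an unadjusted p below 0.05) or without D374Y 2 (800), 1 without control 2 and 496 without D374Y 1, and DESeq2 called 704.

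At week 4, 5 genes were called in D374Y livers (n = 3 and 2), all higher. Saa3 stood at 28.9 ± 9.36 against 2.02 ± 0.796 CPM and Cd5l at 116 ± 27 against 37.3 ± 5.25; the ATP receptor P2rx7 (1.84 ± 0.28) and Tmem86a (1.29 ± 0.23) rose as well. Cytokines (list p 0.00239; 0 of 15 called, 12 adjusted over the list alone), recruited macrophage markers (list p 0.0243; 0 of 13, 5 adjusted over the list alone), acute-phase genes (list p 0.0243; 1 of 18, 7 adjusted over the list alone) and MHC class II genes (list p 0.0443; 0 of 8, 5 adjusted over the list alone) rose on balance. All 5 genes were also called higher in APOE cKO livers at that time, where 0.0622 were due by chance (Fisher's exact p 2.80e-10). The count was 0 without control 2 (edgeR, 779 genes at an unadjusted p below 0.05), 1 without D374Y 3, 3 without D374Y 1 or 2, and 61 in DESeq2.

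In D374Y livers week 8 (n = 5 and 3) had the most called genes of the times, which differ in n and sex: macrophage, cytokine, fibrosis and neutrophil lists rose, and the fatty acid oxidation list fell. Gpnmb stood at 99.8 ± 34.7 against 1.09 ± 0.233 CPM, Cd5l at 733 ± 100 against 176 ± 41.3, Trem2 at 12.6 ± 2.14 against 1.67 ± 0.588 and Saa1 at 173 ± 43.2 against 25.5 ± 12.9. Cd163, the haemoglobin scavenger receptor of resident macrophages, fell to 3.39 ± 2.18 against 30.8 ± 2.58 CPM, while Clec4f rose from 198.7 ± 23.6 to 277 ± 50.7 CPM with overlapping groups (adjusted p 0.032). Large decreases included Cyp4a14 (-2.56 ± 0.77), Cyp4a10 (-2.05 ± 0.57) and Acot1 (-2.25 ± 0.45), which handle fatty acids, and Sult2a3 (-2.11 ± 0.57). Fatty acid oxidation fell in 16 of 18 members (list p 0.00189), with Acadm (-0.77 ± 0.14) and Hadhb (-0.66 ± 0.11). Bile acid genes fell in 3 of 13 (list p 0.00698; Amacr, Baat and Acox2). Fatty acid synthesis rose in 3 of 16 (list p 0.0421), with Acly (1.46 ± 0.37). LXR targets rose in 6 of 10 (list p 1.18e-05), with Abcg1 at 54.5 ± 7.77 against 11.9 ± 1.94 CPM and Lpl (1.63 ± 0.22). The cholesterol synthesis and uptake list was not called (list p 0.231). The lipid droplet list had Fabp4 (1.17 ± 0.17) and Cd36 (0.57 ± 0.11) higher and Plin5 (-0.79 ± 0.13) lower of 11, with a list test of 0.864.

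Immune and stromal lists of D374Y livers at week 8 rose in recruited macrophage markers (9 of 13; list p 1.18e-05), with Lgals3 (2.84 ± 0.31), and cytokines (12 of 15; list p 1.77e-04), with Vcam1 (1.69 ± 0.17). MHC class II genes rose (7 of 8; list p 2.50e-04), with H2-Aa (1.63 ± 0.22). Acute-phase genes rose in 8 of 18 (list p 0.0197), with Orm2 (1.88 ± 0.37). Neutrophil markers rose in 4 of 9 (list p 0.00396), with S100a8 (2.03 ± 0.39), and fibrosis genes in 10 of 14 (list p 4.27e-05), with Col1a1 (1.95 ± 0.26) and Col3a1 (1.34 ± 0.19). Kupffer cell markers had 4 higher and 1 lower of 10 (list p 0.0247). Proliferation had 3 higher of 12 (7 adjusted over the list alone; list p 0.0247), with Mki67 (1.15 ± 0.29, overlapping), and T and NK cell markers 1 of 13, Nkg7 (list p 0.0147). Interferon genes had 6 higher and 1 lower of 16 without a list call (list p 0.0631). Sinusoidal endothelial markers had 2 higher of 11, B cell markers 1 of 11 and the red blood cell list 1 of 4, Alas2 (0.51 ± 0.13, overlapping). In all 1058 genes were higher and 542 lower of 14357, and the sum of 1600 was 937 without control 2.

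At week 12, acute-phase genes were among the largest increases in D374Y livers (n = 4 and 3), with uneven levels between livers. Saa1 stood at 3216 ± 4237 against 27 ± 14.7 CPM, with an SD above the mean, and Saa2 (8.25 ± 1.76), Orm2 (6.63 ± 1.42), Lcn2 (6.40 ± 1.52) and the neutrophil protease gene Prtn3 (13.9 ± 15.7 against 0.0691 ± 0.0715 CPM) had the other largest increases. G0s2, an inhibitor of fat breakdown (-2.88 ± 0.59), Csad of taurine synthesis (-2.24 ± 0.58), Smad7 (-2.22 ± 0.35), Id1 (-2.02 ± 0.39) and Mme (-1.96 ± 0.23) fell. Acute-phase genes rose in 12 of 18 (14 adjusted over the list alone), with a list test of 0.0592, so the balance of the whole list did not pass. Cholesterol synthesis rose in 5 of 24 (8 adjusted over the list alone), with Mvd (1.44 ± 0.26), and fatty acid synthesis in 4 of 16 (6 adjusted over the list alone), with Thrsp (2.30 ± 0.36). Fatty acid oxidation fell in 3 of 18 (6 adjusted over the list alone), with Fgf21 (-1.66 ± 0.44). Cd5l stood at 408 ± 104 against 148 ± 40.2 CPM and Gpnmb at 4.86 ± 2.68 against 0.841 ± 0.542. Clec4f (0.81 ± 0.18), Lgals3 (1.52 ± 0.26), Abcg1 (0.79 ± 0.17) and Acta2, actin of contractile cells (1.47 ± 0.29), rose. Cytokines rose in 3 of 15 and interferon genes in 4 of 16 (10 adjusted over the list alone). Of the circadian clock list 4 of 13 were higher and 1 lower (7 and 3 adjusted over the list alone; list test 0.132), with Dbp (3.20 ± 0.58) and Per3 (3.30 ± 0.64) up and Clock (-0.98 ± 0.12) down. No list passed its test. Of 14459 genes, 394 were higher and 233 lower; the total of 627 was 77 without control 1, 276 without control 2 and 394 without D374Y 3.

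At week 20 in D374Y livers (n = 4 and 2), Mug2 (mm9 chromosome 6, 121956816 to 122035985), a secreted protease inhibitor, stood at 382 ± 42.4 against 68.1 ± 5.66 CPM. At week 8 Mug2 was low in untreated D374Y controls alone, at 146 ± 61.1 CPM. It then stood at 559 ± 88 in D374Y, 552 ± 18.8 in APOE control and 609 ± 61.7 in APOE cKO livers. Whether its level is a response to D374Y or a trait of these controls was not tested. Abcg1 rose to 31.1 ± 9.65 against 9.27 ± 0.8 CPM at week 20. Gdf15, a cytokine of cell stress (2.21 ± 0.23), Tmc3 (6.92 ± 3.49 against 0.275 ± 0.0633 CPM) and Ccdc148 (1.81 ± 0.29) rose. Gulo of vitamin C synthesis (-0.65 ± 0.10), Adh6-ps1 (-0.72 ± 0.086) and Syt1 (-0.84 ± 0.13) fell. Cd5l had a log2 fold change of 1.71 ± 0.32 (adjusted p 0.0694). LXR targets (list p 0.031, 1 called) and sinusoidal endothelial markers (list p 0.031, 0 called) rose on balance, and the sex-linked list moved down (list p 0.0328, 0 of 5 called). All these livers are male, and the member Xist rests on few counts, at 0.0346 ± 0.0401 against 0.179 ± 0.0725 CPM. The list test is therefore no sign of a difference in sex. Adjusted over the list alone, 8 of 12 lipid droplet genes (list test 0.0647), 8 of 13 recruited macrophage markers and 8 of 10 Kupffer cell markers were higher and 1 Kupffer marker lower. The liver D374Y 4 lay closest to the controls in Gpnmb, at 1.32 CPM (D374Y 1 to 3: 21.7, 22.7 and 6.13, controls 0.64 and 0.922). Its Saa1 was 14.4 CPM (D374Y 1 to 3: 112.5, 114.7 and 57.1, controls 12.29 and 22.75). Both genes were chosen after their values were seen. Of 13259 genes 19 were called, 16 higher. Every library left out moved that count: 4 without D374Y 2, 5 without control 2, 7 without D374Y 3, 8 without D374Y 1, 37 without control 1 and 744 without D374Y 4.

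Called higher in D374Y livers at 3 of the 4 HFD times were, among others, Tmc3, with controls at 0 CPM at week 4 and therefore no mean fold, and, in order of mean log2 fold change, Saa3 (2.65), Ccdc148 (1.74), Cd5l (1.72), Abcg1 (1.54), the potassium channel gene Kcna2 (1.46), P2rx7 (1.22), Ano6 (0.80) and Thumpd3 (0.56). None was called at all 4. Lower at 2 times were 45 genes, led by Csad (-1.18), Chrna2 (-0.77), Acot1 (-0.70), Gt(ROSA)26Sor (-0.57), Crot (-0.44), Hsdl2 (-0.43), Aldh3a2 (-0.40), Prkd3 (-0.38), Slc22a5 (-0.35) and Acsl1 (-0.34). The gene models of Thumpd3 (mm9 chromosome 6, 112996321 to 113018267) and Gt(ROSA)26Sor (113017423 to 113027238) overlap, on the chromosome that holds Mug2. A difference at this locus between D374Y mice and their controls was not tested. Weeks 8 and 12 shared 140 higher genes where 28.3 were due by chance (Fisher's exact p 1.43e-62) and 44 lower where 8.58 were due (1.31e-19). The test of change in the D374Y effect from week 4 to week 20, which sets female against male livers, called 0 of 13811 genes in edgeR (1469 at an unadjusted p below 0.05) and 27 in DESeq2; it called 15 without week 4 D374Y 1 or 2 and 1 without week 4 control 1.

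**Figure D2:**
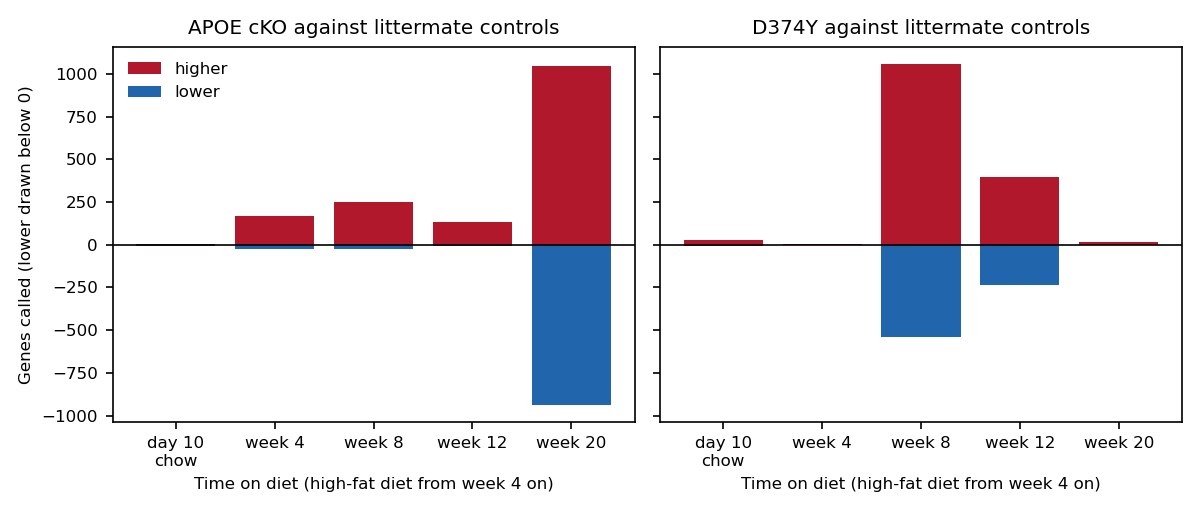
Number of genes called higher (upward bars) and lower (downward bars) against littermate controls at each time in both models. APOE cKO calls peak at week 20 (1044 and 936) and D374Y calls at week 8 (1058 and 542). The times differ in n and sex, and at week 20 leaving out a single library moves the count far in both models.

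Were the responses of both models alike? Over all tested genes their log2 fold changes correlated at Pearson 0.18 at day 10 and 0.31, 0.35, 0.33 and 0.28 at weeks 4, 8, 12 and 20. At week 8, 226 of the 249 genes higher in APOE cKO livers were also higher in D374Y livers, where 18.4 were due by chance (Fisher's exact p 1.52e-235). D374Y livers had 1058 higher genes then, so most of theirs were not shared. At week 12, 72 of 136 were shared (3.71 due, p 2.94e-77). Fisher's test takes genes as independent, which genes that move together are not. At week 20, 8 genes were shared (1.26 due; 1.04e-05). APOE cKO livers at week 8 and D374Y livers at week 12, both male, shared 77 higher genes (6.87 due; 1.68e-60). Among lower genes 1 was shared on chow at day 10 (0.00271 due; 0.00271), 1 at week 8 (1.02 due), 0 at week 12 and 2 at week 20 (0.212 due; 0.0142). The direct test of the difference called 71 genes at week 8, a time at which the APOE cKO series is male and the D374Y series female. Besides Apoe (-2.78 ± 0.15) and Mug2 (-1.79 ± 0.24) the APOE cKO effect was lower for Scd1 (-1.51 ± 0.32), and it was higher for Cyp2a4 (4.83 ± 0.80), Notum (0.99 ± 0.16) and Cd163 (2.75 ± 0.55). The Mug2 difference went with its low level in D374Y controls, 146 ± 61.1 CPM against 552 ± 18.8 in APOE controls. By list, the APOE cKO effect was lower on fatty acid synthesis (list p 0.0282), LXR targets (list p 0.0282) and recruited macrophage markers (list p 0.0411) and higher on fatty acid oxidation (list p 0.0411), with 1, 0, 0 and 0 called members and 15, 4, 5 and 13 adjusted over the list alone. The count was 26 and 34 without APOE controls 3 and 2, 34 and 35 without APOE cKO 4 and 1, 36 and 143 without D374Y controls 2 and 3, and 39, 42 and 39 without D374Y 1, 4 and 5.

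At day 10 the difference test called Apoe alone (-2.25 ± 0.24), and 2 genes without D374Y control 2. At week 4 it called 0 genes in edgeR (567 at an unadjusted p below 0.05) and 1 in DESeq2, with 4 without APOE cKO 3. Apoe was thus not called there in edgeR, although it was called lower in APOE cKO livers at week 4. Its log2 fold change in D374Y livers at that time was 0.10 ± 0.59, so the lack of calls does not show equal effects. At week 12 the difference test called 2 genes, among them Apoe (-2.40 ± 0.15), with 5 genes without D374Y control 1 or D374Y 2 and 4 without D374Y 1. At week 20, with female APOE cKO and male D374Y series, it called 46 genes. Mup20 (3.96 ± 0.49), the calcium-dependent carrier Slc25a25 (2.66 ± 0.31), the oxidase Nox4 (2.51 ± 0.31), Errfi1 (3.09 ± 0.42) and Enpp3 (0.78 ± 0.12) were higher in the APOE cKO effect. Gdf15 (-4.10 ± 0.30), Mug2 (-2.16 ± 0.20), Etnppl (-1.01 ± 0.12), Apoe and Cyp2b9 were lower. Each library left out moved that count: it ranged from 5 without APOE control 2 to 332 without APOE cKO 2, with 6 without APOE control 1, 15 and 20 without APOE cKO 1 and 3, 71 and 18 without D374Y controls 1 and 2, and 12, 11, 28 and 299 without D374Y 1, 2, 3 and 4.

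**Figure D3:**
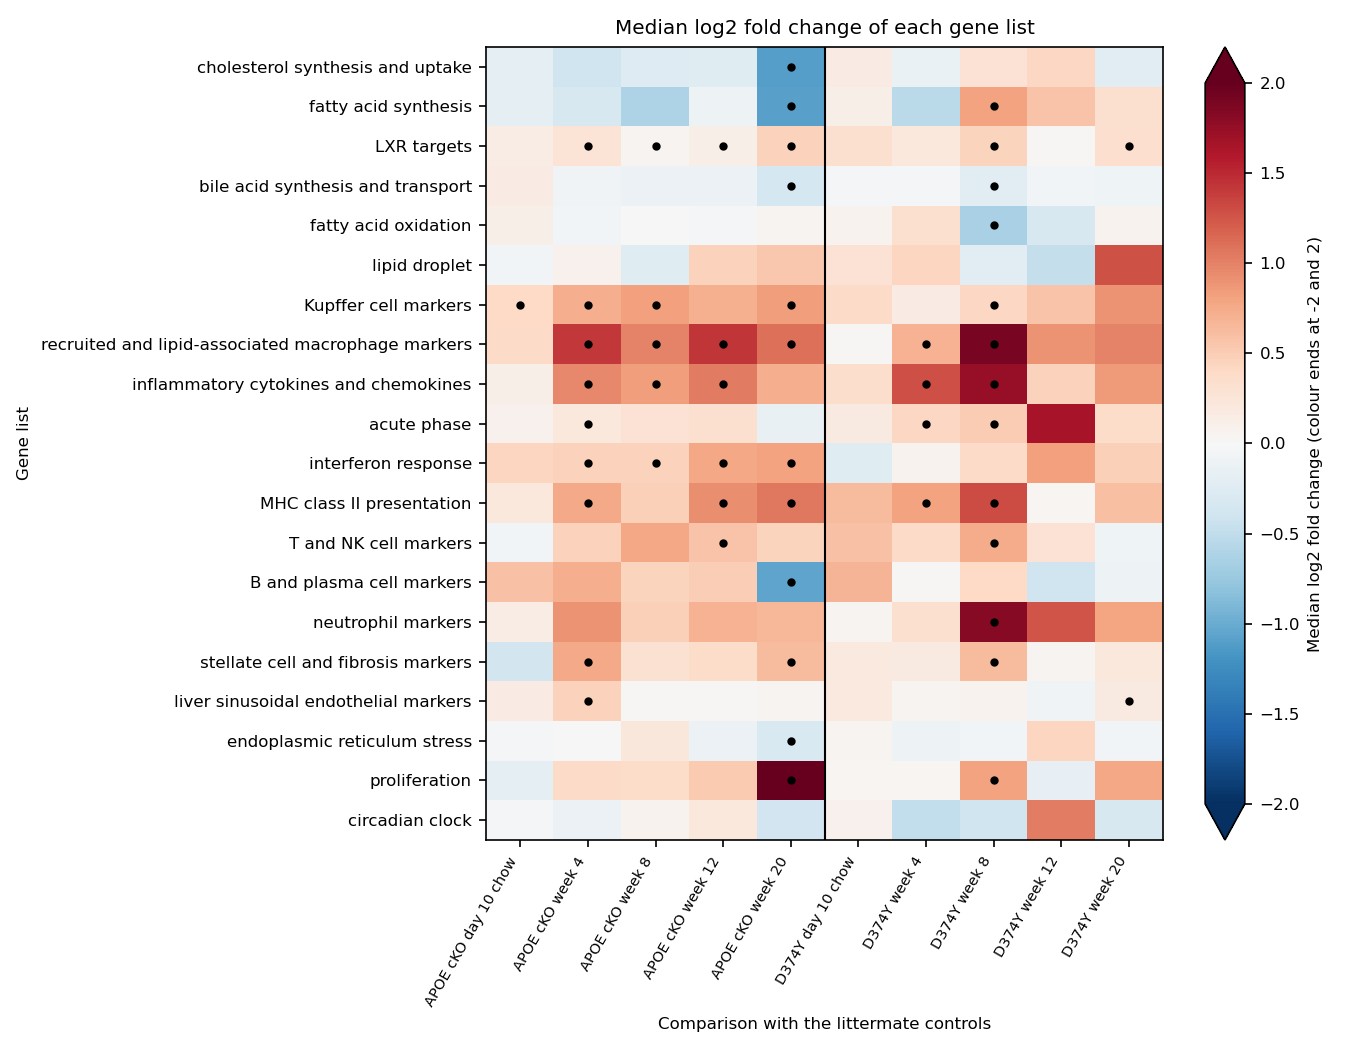
Median log2 fold change of 20 gene lists in the 10 genotype comparisons, with dots where the list's adjusted p is below 0.05. Macrophage, cytokine and LXR lists are above 0 in most HFD comparisons.

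Does removing Kupffer cells change the liver's RNA on chow? In APOE cKO livers at day 10 (n = 3 and 3), clodronate lowered Kupffer markers relative to Dil liposomes: Timd4 stood at 0.0498 ± 0.0863 against 23.5 ± 0.973 CPM, Vsig4, a complement receptor, at 0.641 ± 0.959 against 76.6 ± 11.9, Cd163 at 0.213 ± 0.207 against 46.6 ± 15.1 and Folr2 at 1.13 ± 0.561 against 30.5 ± 3.32. The chemokine Cxcl13 was at 0 ± 0 against 5.3 ± 2.65 CPM. Of the Kupffer list 9 of 10 fell (10 adjusted over the list alone; list p 1.98e-04). Receptors of incoming monocytes rose: Cx3cr1 to 8.4 ± 2.6 against 2.02 ± 0.807 CPM and Ccr2 by log2 1.72 ± 0.25. LXR targets fell on balance (list p 0.0254), with Pltp (-1.42 ± 0.18) and Abcg1 (-0.80 ± 0.14) called, as did Il1b (-2.86 ± 0.50), Cd74 (-1.13 ± 0.19), Cd22 (-2.91 ± 0.27) and Cd68 (-1.35 ± 0.20), members of other lists. Apoe did not change by the test (log2 0.13 ± 0.085). Of 13029 genes 5 rose and 207 fell; the total of 212 was 72 and 115 without Dil 2 and 1 and 129 and 136 without clodronate 3 and 2.

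In the D374Y series at day 10 the markers go against the labels. Libraries labelled littermate control clodronate kept Clec4f at 345 to 367 CPM, while it was 0 to 0.0412 CPM in those labelled D374Y Dil and 0 to 0.0458 CPM in those labelled D374Y clodronate (n = 3 each). Mug2 was 381 to 566, 575 to 759 and 89.7 to 113 CPM in these groups. The comparisons keep the labels as given. Labelled clodronate against labelled Dil in D374Y called 2 genes, among them Mug2 (102 ± 11.7 against 671 ± 92.5 CPM); 4 were called without clodronate 1 and 1 without clodronate 2 or 3. Labelled D374Y clodronate against labelled control clodronate called 1084 genes, 968 lower. Kupffer markers were lower in 10 of 10 (list p 1.36e-16), with Cd5l at 0.196 ± 0.161 against 464 ± 21.6 CPM and Vsig4 at 0.03 ± 0.026 against 119 ± 0.377. Sinusoidal endothelial markers were lower in 9 of 11 (list p 3.40e-06), interferon genes in 10 of 16 (list p 3.77e-05), MHC class II in 6 of 8 and LXR targets in 5 of 10 (list p 1.21e-07). Hamp, the iron hormone hepcidin (2.90 ± 0.48), and Cxcl1 (1.82 ± 0.53) were higher.

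**Figure D4:**
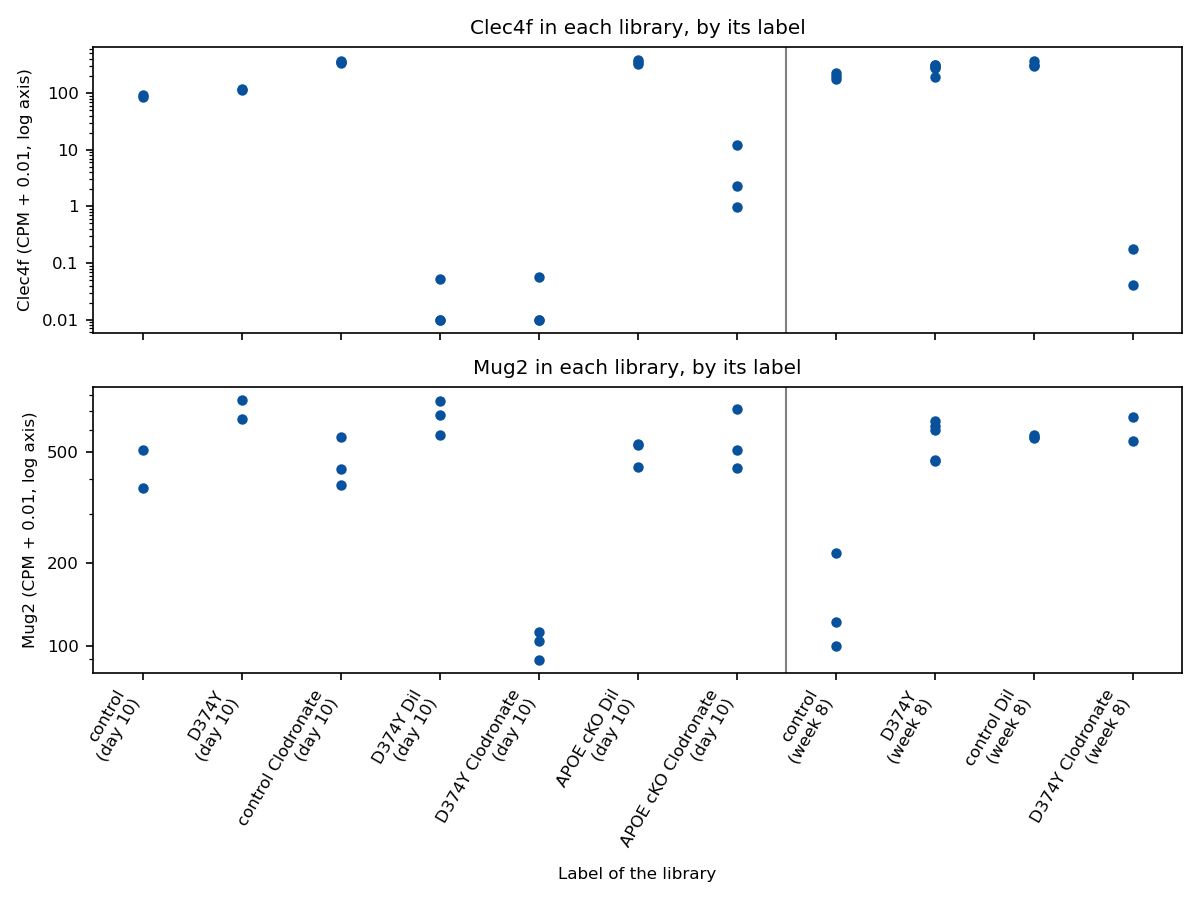
CPM of Clec4f, a Kupffer cell marker, and of Mug2 in each liposome library of day 10 and week 8 and in untreated libraries of the D374Y series, by label, on logarithmic axes after adding 0.01 CPM. The day 10 libraries labelled littermate control clodronate keep Clec4f, and those labelled D374Y Dil lack it. Untreated and liposome libraries of day 10 are of different library sets, so their levels are not on a common scale.

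A comparison added after these levels were seen sets the libraries labelled D374Y Dil, which lack Clec4f, against those labelled littermate control clodronate, which have it. Clec4f is itself a Kupffer marker, so a lower Kupffer list was set by this choice and is no separate evidence. Cd5l stood at 0.143 ± 0.0584 against 464 ± 21.6 CPM and Abcg1 at 8.41 ± 0.627 against 29.3 ± 2.48, and Lpl (-2.50 ± 0.28), Vcam1 (-2.29 ± 0.26) and H2-DMa (-2.05 ± 0.31) were lower, with Kupffer markers lower in 10 of 10 (list p 2.35e-16). Hamp was higher at 796 ± 297 against 119 ± 25.9 CPM, and neutrophil markers were higher in 5 and lower in 1 of 8 (list p 0.0169), with S100a8 (1.86 ± 0.43). Fatty acid oxidation was higher on balance with 0 called (list p 0.0254). Of 13270 genes 78 were higher and 877 lower. Of the 196 genes that fell with clodronate in APOE cKO livers and were tested in both, 191 were lower here as well, where 13.1 were due by chance (Fisher's exact p 1.08e-225).

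A pair of day 10 comparisons cross library sets. Labelled D374Y Dil against untreated D374Y (n = 3 and 2) called 7389 genes, among them Rps29 (0.0907 ± 0.0376 against 379.5 ± 29.1 CPM), and the sets differ in length profile, so treatment and set cannot be separated. Vsig4 was at 0 ± 0 against 315 ± 57.9 CPM, Kupffer markers were lower in 10 of 10 (list p 1.08e-15), the circadian clock list was higher in 6 and lower in 2 of 13 (list p 8.24e-05), and the 1 tested pancreas gene was lower. The difference between the D374Y effect with and without clodronate called 1089 genes, with Gt(ROSA)26Sor (2.41 ± 0.37) among the higher and Clec4f, Vsig4 and Cd5l among the lower, and 568 and 573 without untreated control 1 and untreated D374Y 2.

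At week 8 of HFD, D374Y livers with clodronate (n = 2) had lower Kupffer, interferon and MHC class II transcripts and higher acute-phase transcripts. Against untreated D374Y (n = 5), Clec4f stood at 0.0993 ± 0.0978 against 277 ± 50.7 CPM, Vsig4 at 0.124 ± 0.0803 against 68.2 ± 35.6 and Timd4 at 0.0603 ± 0.0853 against 12.1 ± 6.49, and Cd5l stood at 251 ± 73.4 against 733 ± 100 CPM. Kupffer markers fell in 9 of 10 (10 adjusted over the list alone; list p 4.75e-08). Interferon genes fell in 11 of 16 (list p 9.33e-05), with Mx1 (-2.26 ± 0.22) and Irf7 (-1.19 ± 0.14), and MHC class II in 6 of 8 (list p 0.00408), with H2-Aa (-1.52 ± 0.25). Acute-phase genes rose in 13 of 18 (17 adjusted over the list alone; list p 4.23e-04), with Orm2 (4.80 ± 0.34), Hpx (1.07 ± 0.11) and the metallothionein Mt2 (4.54 ± 0.57). Neutrophil markers rose in 6 of 9 (list p 0.00271), with S100a8 (2.38 ± 0.32), and proliferation in 2 of 12 (6 adjusted over the list alone; list p 0.0135). Scd1 (-1.04 ± 0.28) and Me1 (-1.26 ± 0.33) fell without a call of the fatty acid synthesis list. T and NK cell markers fell on balance with 0 called (list p 0.0241), and Cela1, of the pancreas list, fell (-1.02 ± 0.23). The clock list moved (list p 9.76e-04), 7 of 13 higher and 2 lower, with Dbp (4.69 ± 0.72). Dbp and the clock list also moved in the libraries labelled littermate control Dil against these untreated livers, so this change is not particular to clodronate. In all 364 genes were higher and 367 lower, 731 together and 286 without clodronate 2.

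Against the week 8 libraries labelled littermate control Dil (n = 3), D374Y livers with clodronate had 489 called genes. Clec4f stood at 0.0993 ± 0.0978 against 327 ± 30.5 CPM, and Kupffer markers fell in 10 of 10 (list p 1.69e-08). Interferon genes fell in 12 of 16 (list p 3.62e-05), cytokines in 8 of 15 (list p 0.00186), with Cxcl10 (-2.09 ± 0.36), and MHC class II in 5 of 8 (list p 0.00542). Acute-phase genes rose in 11 of 18 (list p 0.00113) and proliferation in 6 of 12 (list p 0.00113), with Ccna2 (2.37 ± 0.31). LXR targets fell on balance (list p 0.00749), with Lpl called (-0.98 ± 0.27). The count was 250 without clodronate 2 and 307 without Dil 2. In these Dil libraries Mug2 was 560.2 to 573.7 CPM, above the untreated controls (100.5 to 215.7) and within the range of the untreated D374Y libraries (462.6 to 647.7). Comparisons added for that reason called 1644 genes against untreated controls, with Gpnmb at 119 ± 5.96 against 1.09 ± 0.233 CPM and Cd5l at 831 ± 43.5 against 176 ± 41.3, and recruited macrophage markers higher in 10 of 13 (list p 6.79e-06). Against untreated D374Y they called 161 genes. Clock genes such as Dbp (5.00 ± 0.68) and Per3 (3.68 ± 0.58) were higher and Npas2 (-3.20 ± 0.53) lower, 6 and 3 of 13 (list p 0.00384). That count was 13 and 28 without Dil 2 and 1, and 70, 73, 96 and 105 without D374Y 2, 1, 3 and 4.

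What did lymphocyte antibodies change at week 4? With the CD20 antibody, B cell transcripts of D374Y livers fell relative to PBS (n = 3 and 2). The immunoglobulin gene IGHD stood at 0.113 ± 0.152 against 10 ± 0.869 CPM, Cd79b at 0.733 ± 0.375 against 6.12 ± 0.123, Cd79a at 0.398 ± 0.209 against 5.18 ± 0.388 and Fcer2a at 0 ± 0 against 3.02 ± 0.913. B and plasma cell markers fell in 8 of 13 (10 adjusted over the list alone; list p 2.18e-04), and no other list was called. Dmbt1, a mucosal glycoprotein, stood at 1.72 ± 1.67 against 90 ± 52.9 CPM; the PBS libraries (127.4 and 52.57) stand apart here, since the untreated and CD8 libraries of week 4 had at most 0.1876. Of 13596 genes 25 were called, all lower; the count was 6 and 10 without PBS 2 and 1, and 16 and 13 without CD20 1 and 3. The label of CD20 replicate 3 is in doubt: it had 1895 CPM of Apoe against 22140 and 25120 CPM in the other two, and 0 of Cyp2b9 against 297.3 and 409.

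The CD8 antibody was set against untreated livers of the same genotype. In APOE cKO livers (n = 2 and 3), Timd4 stood at 0.395 ± 0.0545 against 43.1 ± 9.3 CPM, Vsig4 at 9.48 ± 3.15 against 144 ± 13.6 and Clec4f at 8.47 ± 2.74 against 98.5 ± 18.3, and Kupffer markers fell in 6 of 10 (9 adjusted over the list alone; list p 3.39e-07). Cx3cr1 rose to 24 ± 2.35 against 2.54 ± 0.984 CPM and Gpnmb to 88.6 ± 24.1 against 13.2 ± 0.369, while Ccl2 fell to 0.729 ± 0.315 against 5.11 ± 1.76. Cytokines fell in 3 of 15 (list p 7.34e-04), with Cxcl9 (-1.95 ± 0.38). Interferon genes fell on balance (list p 0.0434). Recruited macrophage markers rose in 3 of 13 (list p 0.0434) and fibrosis genes in 2 of 14 (list p 0.0229), with Col3a1 (1.89 ± 0.38). T and NK cell markers had 0 called members (list p 0.0871). The 60 called genes (16 higher) were 12 and 18 without CD8 1 and 2 and 31 without untreated 1.

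In D374Y livers the comparison with untreated livers (n = 3 and 3), added after the library sets were seen, gave Timd4 at 1.03 ± 0.321 against 28.9 ± 3.63 CPM, Clec4f at 3.18 ± 1.24 against 56 ± 13.7 and Vsig4 at 22.4 ± 5.33 against 166 ± 53.1. Kupffer markers fell in 6 of 10 (8 adjusted over the list alone; list p 1.73e-07) and cytokines in 4 of 15 (list p 5.35e-04), with Ccl2 (-2.61 ± 0.34) and Cxcl10 (-2.07 ± 0.27). Fibrosis genes rose in 6 of 14 (10 adjusted over the list alone; list p 5.35e-04), with Col1a1 (2.66 ± 0.46) and Lum (1.79 ± 0.32), as did Orm2, to 827 ± 250.5 against 80.2 ± 15.5 CPM, and Cx3cr1 (2.19 ± 0.35). Of 72 called genes 42 were higher, with 40 called without CD8 2. Both CD8 comparisons shared 15 higher and 27 lower genes, where 0.0494 and 0.0971 were due by chance (Fisher's exact p 2.07e-38 and 7.76e-69).

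The PBS libraries belong to another library set than the untreated and CD8 libraries, so treatment and set cannot be separated in the remaining pair of comparisons. PBS against untreated D374Y (n = 2 and 3) called 6851 genes, with Rps29 at 518 ± 102 against 0.0769 ± 0.133 CPM and Dmbt1 at 90 ± 52.9 against 0 ± 0. Sinusoidal endothelial markers were lower in 9 of 11 (list p 1.69e-06), MHC class II higher in 5 of 8 (list p 0.0043), and Kupffer markers went both ways (4 higher and 5 lower, median -0.64, mean 0.23, upward test 0.989). CD8 against PBS (n = 3 and 2) called 7163 genes, with Kupffer markers lower in 7 and higher in 1 of 10 (list p 3.50e-07), fibrosis genes higher in 11 and lower in 1 of 14 and sinusoidal endothelial markers higher in 10 of 11.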

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

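The 4 checks of the Cyp2b9 and Cyp2b13 levels were chosen only after those levels had been seen.

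In groups of 4 or 5 libraries, 15 genes were searched for a library far from the others of its group, which chance gives in about 1 in 20 groups. Of 111 such tests 9 found one. Apoe was 2930 CPM in APOE cKO replicate 2 at week 12 (others 2700 to 2733), and Gpnmb was 8.88 CPM in D374Y replicate 3 at week 12 (others 3.30 to 3.81). At day 10, APOE cKO replicate 2 had 356 CPM of Mug2 (others 403 to 411), and APOE cKO replicate 3 had 120.3 of Cd5l (others 168 to 175). At week 8, D374Y replicate 5 had 5.34 CPM of Vsig4 (others 77 to 91.9), D374Y replicate 2 had 557 of Cd5l (others 759 to 808), and D374Y replicate 4 had 384 of Cyp2b9 (others 429 to 443). Cyp2b9 was also 0.0416 CPM in APOE cKO replicate 2 at week 8 and 0.0164 in D374Y replicate 2 at week 12, in groups with 0 in the others, so each stands for few counts. D374Y replicate 5 at week 8 was also lowest of its group in Timd4 (2.69 CPM, others 9.92 to 19.8) and Cd163 (0.269, others 2.02 to 5.39). Its Adgre1 lay within the others (58.5, others 50.7 to 62.5). These genes were chosen after their values were seen. This library is in every week 8 comparison with untreated D374Y.

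Differences between the models were found by a test of the difference of the genotype effects. At day 10 the 1 gene was Apoe (-2.25 ± 0.24; 1 to 2 genes with 1 library left out). At week 8, 71 genes differed (26 to 143 with 1 library left out): Notum (0.99 ± 0.16), Cyp2a4 (4.83 ± 0.80), Adtrp (0.70 ± 0.12), Epb41l4b (0.51 ± 0.089) and Fgf1 (0.81 ± 0.14) had the smallest adjusted p among those higher in the APOE cKO effect, and Apoe (-2.78 ± 0.15), Mug2 (-1.79 ± 0.24), Pgrmc2 (-0.74 ± 0.11) and Gusb (-0.75 ± 0.12) among those lower. Fatty acid synthesis (list p 0.0282), LXR targets (list p 0.0282), fatty acid oxidation (list p 0.0411) and recruited macrophage markers (list p 0.0411) differed as lists. At week 12, 2 genes differed, among them Apoe (-2.40 ± 0.15; 2 to 5 genes with 1 library left out). At week 20, 46 genes differed (5 to 332 with 1 library left out): Slc25a25 (2.66 ± 0.31), Mup20 (3.96 ± 0.49), Nox4 (2.51 ± 0.31), Errfi1 (3.09 ± 0.42) and Enpp3 (0.78 ± 0.12) higher, and Apoe (-3.01 ± 0.16), Gdf15 (-4.10 ± 0.30), Mug2 (-2.16 ± 0.20), Etnppl (-1.01 ± 0.12) and Cyp2b9 (adjusted p 0.00112) lower. The models are of opposite sex at weeks 8 and 20, so a difference of sex cannot be told apart from a difference of model there.

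Between weeks 4 and 20 the APOE cKO effect changed, by a test of that change, for 13 genes (2 to 44 with 1 library left out). Those named by the rule were Mup20 (4.99 ± 0.54), Ugt2b35 (1.23 ± 0.20), Ccnyl1 (1.76 ± 0.34), C8a (1.59 ± 0.31), Mzt1 (0.76 ± 0.15), Cyp3a44 (-3.78 ± 0.62), Cyp3a16 (-4.86 ± 0.91), Atp1b3 (-1.27 ± 0.25) and Cyp17a1 (-2.65 ± 0.55), and the B and plasma cell list (list p 0.0406). The week 4 and week 20 libraries have different length profiles, shared by both genotypes within each week.

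The D374Y effect at day 10 differed with and without labelled clodronate for 1089 genes (568 to 1308 with 1 library left out). Lists that differed were LXR targets (list p 1.76e-06), Kupffer cell markers (list p 2.74e-15), recruited macrophage markers (list p 3.71e-06), cytokines (list p 9.54e-04), interferon genes (list p 0.0038), MHC class II (list p 7.33e-04), T and NK cell markers (list p 0.00125) and sinusoidal endothelial markers (list p 4.93e-05). The markers of the clodronate libraries go against their labels, so this difference does not answer whether clodronate alters the genotype effect.

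In female APOE cKO libraries, Cyp2b9 and Cyp2b13 were near 0 at week 20 (Cyp2b9 0.0185 ± 0.032 against 319 ± 12.4 CPM, n = 3 and 2) and in a part of those at week 4 (0.125, 0.613 and 778 CPM of Cyp2b9 in the 3 untreated libraries, 0 in both CD8 libraries). Sex was read here from Xist and Ddx3y, not from a label, so a wrong sex label could not be tested. The lowest Xist level of the APOE cKO libraries of weeks 4 and 20 was 348.5 CPM. The low Cyp2b9 levels thus do not come from libraries read as male. A loss of the whole female-type difference in general is argued against by a median log2 change of -0.74 (SD 1.58) at week 20 over 63 genes more than 8-fold higher in female APOE controls than in male D374Y controls, where the median difference is 4.60. Of these 63, 23 were called lower, so a partial loss stays open; the difference also holds any between the models. A variant near Apoe in every APOE cKO mouse is argued against by the day 10 libraries, whose lowest Cyp2b9 level was 282 CPM. A variant carried by some of these mice stays open: Cyp2b9 and Cyp2b13 lie within 10 Mb of Apoe, but 34 of 211 tested genes in that window were called at week 20, no more than elsewhere (odds ratio 1.10, Fisher's exact p 0.626, two-sided), and a variant of these genes alone needs no others. An effect of Apoe loss on these genes under HFD is a hypothesis that may also hold and was not tested.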

How the results depend on the processing

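The fits with libraries of one length profile, the fit without D374Y 3 and CD8 3 together and the overlaps at an adjusted p under 0.1 were chosen only after the results had been seen.

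No value of a gene, list or count reversed under any alternative that gave one; 9 values of named genes and lists had no adjusted p. Of the values of named genes, 1350 of 1451 kept their direction and side of the threshold in DESeq2 (6 became weaker, 94 stronger), 1448 of 1460 with RLE scaling (9 weaker, 1 stronger), 1415 of 1460 with no low-count filter (12 weaker, 32 stronger), 544 of 599 with Xist as a covariate (41 weaker, 3 stronger), 1318 of 1460 with the replicate block (115 weaker, 24 stronger), 1240 of 1442 with only the compared groups in the fit (160 weaker, 40 stronger), 304 of 340 with one length profile (31 weaker, 4 stronger) and 8191 of 9683 with 1 library left out (1323 weaker, 86 stronger). Of the values of lists, 644 of 654 did so with RLE scaling, 638 of 654 with no low-count filter, 598 of 654 with the replicate block, 561 of 640 with only the compared groups in the fit, 232 of 252 with the Xist covariate, 226 of 240 with one length profile and 4317 of 4934 with 1 library left out. With 1 library left out, 192 list values became weaker and 80 stronger. A further 345 list values and 83 gene values then moved in other ways, without counting as reversed. RLE scaling left every count of calls within 1.5 times its value.

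DESeq2 called more genes than edgeR where the counts moved: 84 against 12 in APOE cKO and 704 against 31 in D374Y at day 10, 327 against 195 and 61 against 5 at week 4, 371 against 143 and 1273 against 627 at week 12, and 337 against 19 in D374Y at week 20. Differences between models gave 1 against 0 at week 4, 305 against 71 at week 8, 73 against 2 at week 12 and 418 against 46 at week 20, and changes with time 88 against 13 in APOE cKO and 27 against 0 in D374Y. Clodronate against Dil in APOE cKO gave 379 against 212, and the CD8 antibody in APOE cKO 99 against 60. The cause was not tested.

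With no low-count filter, more genes were called in D374Y at week 4 (49 in place of 5) and week 20 (87, not 19), with CD20 (49, not 25), with CD8 in APOE cKO (101, not 60) and in the difference between models at weeks 4 (1, not 0), 12 (5, not 2) and 20 (102, not 46); the cause was not tested. With Xist as a covariate, D374Y at week 20 and the difference between models at week 20 each had 2 genes called; the cause was not tested.

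With the replicate block, in which libraries of the same number share a block, the counts that moved were 21 in APOE cKO and 10 in D374Y at day 10, 2 in their difference, 131 for clodronate in APOE cKO, 15 with CD20, 405 for clodronate in D374Y at week 8, 49 in APOE cKO and 365 in D374Y at week 12, 960 in D374Y at week 20, and 41 and 396 in the difference between models at weeks 8 and 20. Numbers do not pair the libraries by any label. At day 10 each of 4 APOE cKO libraries correlated best with the control of its own number, at 0.0535 to 0.372, and at week 4 each of 3, at 0.0685 to 0.0966. The cause of the moves was not tested.

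With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, 1 gene was called in APOE cKO and 4 in D374Y at day 10, 123 and 12 at week 4, 147 in D374Y at week 12 and 9 at week 20. The count was 1748 for the difference with and without clodronate at day 10, 254 for clodronate against labelled control Dil at week 8, 5 with CD20 and 2 for the change of the APOE cKO effect with time. With libraries of one length profile, again fewer, the count was 4 in APOE cKO and 0 in D374Y at day 10 (edgeR; 2018 genes at an unadjusted p below 0.05, DESeq2 on all libraries 704), 8 in D374Y at week 4 and 5 with CD20. D374Y at week 4 without D374Y 3 and CD8 3 together had 3 genes called.

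Leaving out 1 library in turn leaves fewer samples, and a lone library of a group is then assumed to vary like the other groups. Counts of calls ranged, at day 10, from 3 to 129 in APOE cKO, 0 to 496 in D374Y, 1 to 2 in their difference, 1 to 4 for labelled clodronate in D374Y, 568 to 1308 for the difference with and without clodronate, and 72 to 183 for clodronate in APOE cKO. At week 4 they ranged from 67 to 188 in APOE cKO, 0 to 4 in D374Y, 0 to 4 in their difference, 12 to 67 with CD8 in APOE cKO and 6 to 19 with CD20. At week 8 they ranged from 124 to 258 in APOE cKO, 937 to 1641 in D374Y, 26 to 143 in their difference, 286 to 915 for clodronate against untreated and 250 to 605 against labelled control Dil. At weeks 12 and 20 they ranged from 32 to 195 and 79 to 1991 in APOE cKO, 77 to 633 and 4 to 744 in D374Y, and 2 to 5 and 5 to 332 in their difference. Changes with time gave 2 to 44 in APOE cKO and 0 to 15 in D374Y.

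At an adjusted p under 0.1, which admits more calls, the models shared 7 higher genes at day 10, 15 at week 4, 125 at week 12 and 70 at week 20, and 3, 10 and 13 lower genes at weeks 8, 12 and 20. In APOE cKO, weeks 4 and 12 then shared 112 higher genes and weeks 12 and 20 shared 189; lower genes shared were 3 (weeks 4 and 8), 2 (4 and 12), 22 (4 and 20), 5 (8 and 12), 19 (8 and 20) and 5 (12 and 20). In D374Y, higher genes shared were 16 (weeks 4 and 8), 14 (4 and 12), 8 (4 and 20), 251 (8 and 12), 65 (8 and 20) and 45 (12 and 20), and lower genes 103 (8 and 12), 7 (8 and 20) and 1 (12 and 20).

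Genes higher in APOE cKO at 3 or more times numbered 205 in DESeq2 and 82 with the replicate block, and at all 4 times 101 and 25. Genes lower in APOE cKO at 2 or more numbered 38 in DESeq2, 8 with only the compared groups and 9 with the replicate block. Genes higher in D374Y at 3 or more numbered 105 in DESeq2, 37 with no low-count filter and 51 with the replicate block, and genes lower at 2 or more 106 in DESeq2 and 9 with only the compared groups. The cause was not tested.

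Depth limits what a level near 0 means: the smallest library held 8691802 counts, and Cyp2b9 at 0.0555 CPM in week 20 was 1 count. In simulated data at these sizes, 36 to 76 of 100 genes changed 2-fold were found.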

Other observations

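The tests of the liposome labels and of the Kupffer cell markers with the CD8 antibody were chosen only after those levels had been seen.

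In the liposome libraries, marker genes go against the labels. At day 10 the libraries labelled littermate control clodronate have Clec4f at 345 to 367 CPM, while those labelled D374Y Dil have at most 0.0412 CPM. Failed depletion in the libraries labelled littermate control Clodronate as the whole source is argued against by the libraries labelled D374Y Dil, in which 10 of 10 Kupffer cell markers were called lower than in these. That comparison was chosen by Clec4f, a member of the list, so the argument rests on the marker levels and not on the list test. A mislabelled sample at day 10, that is, a set of 9 libraries with exchanged labels, stays open. Of 10 genes outside the macrophage lists called higher in untreated D374Y livers at 2 or more of weeks 4, 12 and 20, 4 were lower in labelled D374Y clodronate than in labelled D374Y Dil, 1 of them called and the other 6 higher without a call, which does not decide. Mug2 (-2.17 ± 0.20) and Gt(ROSA)26Sor (0.80 ± 0.22) differ between labelled D374Y and labelled control clodronate with the sign opposite to week 8, but they were picked for this pattern, and Thumpd3, picked with them, was not called. A mislabelled sample at week 8, D374Y mice under the label littermate control Dil, may be the source there: of the same 10 genes 9 were called higher in these libraries than in untreated controls, and against untreated D374Y 0 were called in edgeR (0 at an unadjusted p below 0.05) and 0 in DESeq2. An effect of Dil liposomes on these genes stays open, since no comparison isolates it. The labels of neither set were changed in any comparison.

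With the CD8 antibody at week 4, Kupffer cell markers were lower in both genotypes. A difference in library length profile is argued against by the slopes, since 5 of 5 CD8 libraries lie inside the range of the untreated libraries. Cd8a plus Cd8b1 stood at 0.170 ± 0.149 CPM in 5 CD8 libraries and 1.76 ± 0.47 in 6 untreated (exact permutation p 0.00216, one-sided, 462 splits). No clodronate library entered that test, so it cannot decide whether samples of the clodronate series stand under a CD8 label. A lower share of every cell type other than hepatocytes is argued against by a median log2 change of 0.139 for sinusoidal endothelial markers in D374Y, against -2.52 for Kupffer cell markers. What also stays open is whether the antibody, the injections or the handling of that set of mice is the source, since PBS and CD20 libraries belong to another library set. An effect of CD8 depletion on Kupffer cells may be among these, as a hypothesis only.

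The libraries of each comparison with at least 3 samples per group were also split in other ways into groups of the same sizes. For APOE cKO against control at week 8, 1 of 56 splits gave as many calls as the real split, which is among them (276 genes, highest other 15). At week 12 it was 1 of 35 (143, highest other 25). For D374Y it was 1 of 56 at week 8 (1600, highest other 5) and 1 of 35 at week 12 (627, highest other 96). Each share is below 0.05, with no adjustment over the comparisons split. The splits take libraries as independent, so an effect of litter or batch, which the labels do not give, is not excluded. The libraries labelled control Dil against untreated D374Y at week 8 also had a share below 0.05 (1 of 56 splits, 161 genes, highest other 2). That comparison was added after its marker levels were seen. Chance is not excluded for APOE cKO at day 10, where 4 of 35 splits called as many as 12 genes. There the split that moves control 2 called 2309, a sign of a structure of the samples. For differences between models, the splits exchanged genotypes within each model. They mimic no genotype effect in either model, not equal effects, so they cannot decide whether chance made a difference between models. At week 8, 2 of 100 splits called at least 71 genes, the real split (71) and another (263), which points to a structure of the samples. At week 12, 11 of 100 called at least the 2 genes of the real split (highest other 60).

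Groups of 3 and 3 make 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, reached its count in each of these. That split called 195 genes for APOE cKO at week 4 (highest other 0), 212 for clodronate in APOE cKO at day 10 (0), 2 for labelled clodronate in D374Y (0), 1084 for labelled D374Y against control with clodronate (0), 955 for labelled D374Y Dil against labelled control clodronate (0), 72 for CD8 in D374Y (0) and 1644 for labelled control Dil against untreated control at week 8 (1).

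The library labelled D374Y CD20 replicate 3 had 0 CPM of Cyp2b9 (the other two 297.3 and 409), 22.69 of Gt(ROSA)26Sor (11.54 and 9.357) and 1895 of Apoe (22140 and 25120). Its genotype label is therefore in doubt, and with it the CD20 comparison, which called 13 genes without this library. It had 1210 CPM of Xist and 0 of Ddx3y, as female livers do.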
